A study of Scyliorhinus retifer with 4 samples.

How the data were processed

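Poly(A) RNA of 4 tissues from 1 adult animal was made into stranded libraries with the Illumina TruSeq kit after storage in RNAlater and Trizol extraction, per the labels' protocols. The deposited files give, for each library, an expected count and a TPM value for each of 138659 assembly features. The authors estimated these counts with RSEM 1.1.17, per the submitters' processing notes, and expected counts need not be whole. The deposited TPM values are length-scaled abundances that sum to nearly the same total in each library, and the deposited files give a length per feature that differs between libraries, per the file headers and values. A deposited sequence file holds 169852 assembled transcripts whose headers have the form that Trinity writes, per the file headers. The aligner, the assembler and its version are not given in the sources used here. Features are clusters of assembled transcripts, so 1 gene can be split over several features and related genes can share reads. No reference genome or annotation was used, and no genomic coordinates are given.

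Each library was taken as its tissue from the source label, 1 library per tissue. Expected counts were rounded to whole numbers. Scaling factors were TMM factors from edgeR 4.0.16 (R 4.3.3), at 1.22 for ampullary cells, 1.16 for brain, 0.890 for body skin and 0.791 for muscle, and normalized CPM are counts over the library total times its factor. A feature passed the rule of size for a tissue at a ratio of at least 4 over each other tissue, with a pseudocount of 1 CPM added to both sides, and at least 50 counts in the higher library. Fold ratios printed for single features and sums carry no pseudocount. Values printed as log2 ratios carry the pseudocount of 1 CPM, or 1 TPM with the authors' TPM, unless another is named. With 1 library per tissue no test was made and no p-value is given. Counts have exact Poisson intervals, ratios exact conditional binomial intervals and shares exact Clopper-Pearson intervals, all at 95% and for counting error only. A ratio against a library at 0 counts is set against 3 counts and printed as at least that ratio. It has no interval and is not the lower end of a 95% interval. The 3 counts correspond to 0.121 CPM in ampullary cells, 0.196 in brain, 0.246 in body skin and 0.327 in muscle.

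Names came from sequence matches. Protein sequences of 155 human genes or parts of them were written by hand from memory and were not checked against a database, so an error in one can misname a feature. They were searched against the translated assembly with tblastn (BLAST+ 2.17.0). A feature took the name of its highest-scoring sequence at E of at most 1e-10, at least 50% identity and at least 60 aligned residues, which named 643 features after 133 genes. Of the 155 sequences, 131 were written before any expression value of a feature was seen. The other 23 were added, for genes of the lists and markers that lacked one, after values of features matched by the first set had been seen. The SLC1A2 sequence was replaced at the same time, because the first version was recognised as a mix with SLC1A3; counts of its closest feature had been seen by then. The added sequences named the GFI1, EYA1, EYA4, LHX3, FOXI1, PROX1, CABP1, ATP2B2 and SLC1A3 features among others, and the results without them are in the closing section. The human reading of a label is open wherever a related gene had no sequence in the set. Many genes of the lists and markers had no sequence in the set, so an unmatched gene may never have been searched for.

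Lists of genes, cell type markers and the rule for named genes were fixed before the data were examined. Any list member or marker may be named, then the 15 matched genes with the highest ratio in ampullary cells and 5 for each other tissue at 5 or more CPM, of which 8 qualified in ampullary cells and 3 in body skin. Features of 1 gene were summed for lists and families. Results for some genes are not reported here, and the test of brain RNA in the closing section was recomputed without them. Single features are printed where a sum mixed related genes, and those, including the SLC17A6, POU4F1 and CTBP1 labels, were picked out after their values were seen. For a list with at least 3 genes at 50 counts, the median log2 ratio of ampullary cells over the mean of the other tissues was set among 10000 random lists, each member drawn from the 200 features nearest in mean expression. This percentile describes these libraries and is no test of tissues.

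The rule was tested on simulated data for the comparison of ampullary cells with each other tissue, on Poisson counts drawn for 138659 features from their mean level and the real library sizes, with 200 changed. It called 0 of 50 features changed 2-fold, 47 of 50 changed 6-fold, 49 of 50 changed 8-fold and 50 of 50 changed 16-fold, and 0 of the 138459 unchanged ones. The changed features were drawn from those with at least 50 expected counts in ampullary cells before the change. Recovery of rarer features was not simulated. The true ratio lay inside the interval for 192 of 200 simulated pairs of ampullary cells and brain. The simulation holds no variation between animals. Alternatives covered library totals, DESeq2 1.42.0 size factors, the authors' TPM, other count minimums, ratios and pseudocounts, leaving out the 20 features with the most counts, a match at 65% identity and 1 feature per gene. Added after the data were seen were equal depth, the feature with the highest alignment score, and the first-written sequences alone. Tables and intervals were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.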

Results

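RNA was sequenced from 4 tissues of 1 adult chain catshark (Scyliorhinus retifer), a small bottom-dwelling shark that senses weak electric fields through the ampullae of Lorenzini. The tissues were the ampullary receptor cells, the brain, body skin that lacks these organs, and skeletal muscle, with 1 library each. One label of the brain library names the forebrain, so its values may not stand for other brain regions. The libraries held 20267019 estimated fragments for ampullary cells, 13148583 for brain, 13708891 for body skin and 11603967 for muscle, over 138659 features of a transcriptome assembled from the species. At least 50 counts were reached by 20450 features in ampullary cells, 18763 in brain, 15479 in body skin and 13257 in muscle. There were no replicates, so no difference below has a replicate check and no test between tissues was possible. Values are TMM-normalized CPM (counts scaled to a common library size) with 95% exact Poisson intervals, and ratios carry 95% exact conditional binomial intervals. Both cover counting error only. The features carry no gene names in the files, so each named feature carries the name of the hand-written human protein that its translated sequence matched best. Several features can share a name, and a feature called closest to a gene need not be the best match of that gene. A related gene with no such sequence could carry the same label.

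The first comparison asked which genes set the ampullary cells apart from each other tissue. At a ratio of at least 4 over every other tissue and at least 50 counts, 635 features passed in ampullary cells, against 2303 in brain, 1349 in body skin and 726 in muscle. Among the matched features, 22 passed in ampullary cells, and they included transcription factors of hair cell development, a parvalbumin-type calcium buffer, a calcium pump, a vesicular glutamate transporter and subunits of potassium channels. A feature whose best match was oncomodulin (OCM, c78973_g1), a small calcium-binding protein of the parvalbumin family known from hair cells, was the most abundant of them at 6332 CPM (interval 6300.3 to 6363). It stood at 1.63 in brain, 0.738 in body skin and 2.07 in muscle, and was 3059.5-fold (1959 to 5082) above muscle. Its identity to the OCM sequence was 57.8% over 109 residues, so it is described here as a parvalbumin-family feature. With the feature of the highest alignment score to OCM in its place the log2 ratio over the highest other tissue was -0.10. That value includes a pseudocount of 1 CPM, so for a feature with few counts it does not show equal levels. A feature closest to ATP2B2 (c42752_g1), a plasma membrane calcium pump, reached 1061 CPM and was 13.1-fold (12.1 to 14.1) above muscle, the next tissue. A second ATP2B2-like feature (c63177_g1) had the opposite pattern, with 29.1 CPM in ampullary cells and 850.6 in brain.

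Transcription factors of hair cells and electroreceptors had the highest median of the lists tested. Of the 16 listed genes 11 could be measured. Against the mean of the other tissues on the log2 scale, 9 of these had a ratio above 0. The median was 2.69, which lay at percentile 100 of 10000 random lists matched on mean expression. The 9 included the SOX2 and GFI1 sums, which were highest in brain and in muscle. POU4F1, the label of the next feature, is not a member of the list. The POU4-type feature (c66429_g1), of a family that drives hair cell differentiation, had 131 CPM in ampullary cells and no counts elsewhere, which put it at least 401-fold higher than in muscle, the shallowest library. The sum of the 5 features closest to POU4F1 was 147.5 in ampullary cells, 15.6 in brain and 10.5 in body skin, a ratio of 9.48 (8.32 to 10.9) over brain. The single feature scored 301 bits against POU4F1 and 300 against POU4F3, so the data do not separate the pair. ATOH1 (c52945_g1), the factor that starts hair cell formation, had 9.34 CPM (8.17 to 10.6) in ampullary cells, 0.131 in brain, 0.082 in body skin and no counts in muscle. GFI1 (c70486_g1), which acts downstream of it, had 86.3 against 6.75 in muscle, a ratio of 12.8 (9.93 to 16.7). The sum of all features closest to GFI1 had the opposite order, at 167 in ampullary cells and 267 in muscle. EYA4 (c65593_g2), a cofactor of sensory placode genes, had 342 CPM against 45.9 in muscle, and SIX2 (c13963_g1) had 10.8 against 0.545 in muscle. LHX3 (c56876_g1) had 13.0 and an EYA1-like feature (c68346_g1) 14.7, and neither had a count in the other tissues. The other EYA1-like feature (c61780_g1) held most of the EYA1 counts, at 167 in ampullary cells, 78.4 in muscle and 19.5 in brain, and the EYA1 sum was 2.31-fold (2.14 to 2.51) above muscle. The LHX3 feature and the first EYA1-like feature were at least 39.7-fold and at least 44.9-fold higher than in muscle. Other features went another way. SOX2 (c55365_g1) had 87.3 against 144 in brain, and NEUROD1 (c24513_g1) had 5.70 against 192 in brain. Several sums in this group mix related genes, since 46 features fell closest to GFI1, 16 to FOXI1 and 14 to SOX2. The FOXI1 sum was lowest in ampullary cells, at 127 against 265 in body skin, 173 in muscle and 142 in brain. A FOXI1 feature at full identity, given in the closing section, was instead higher in ampullary cells than in body skin.

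**Figure D1:**
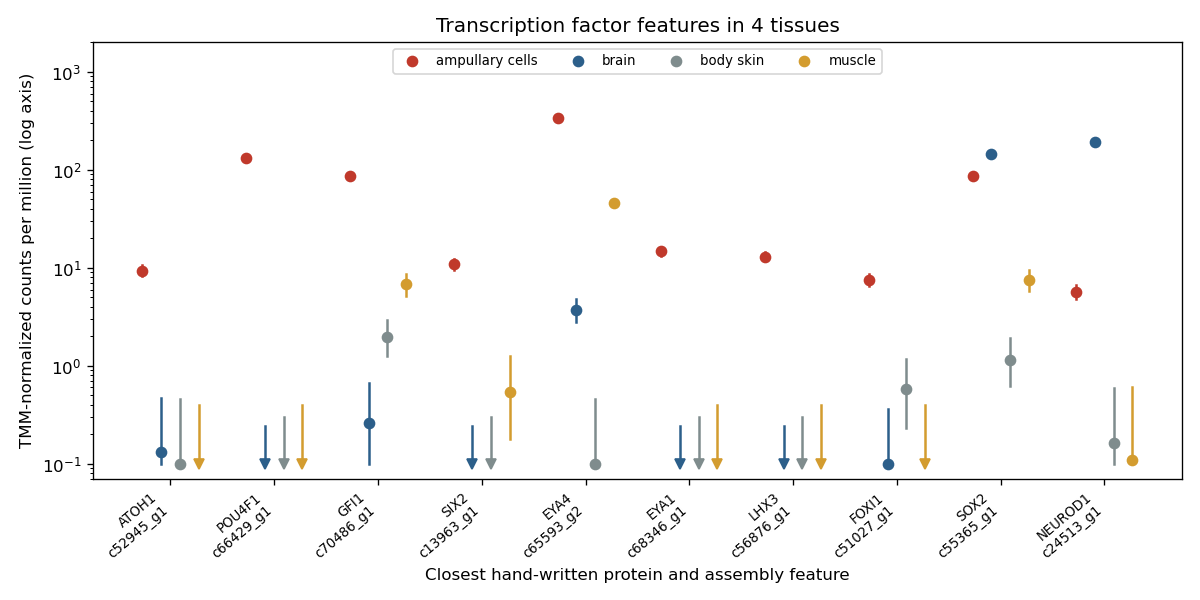
TMM-normalized CPM (log axis) of 10 transcription factor features in the 4 tissues, 1 library each; lines are 95% exact Poisson intervals for counting error only, values under 0.1 are drawn at 0.1, and triangles mark a count of 0. ATOH1, POU4F1, GFI1, SIX2, EYA4, EYA1 and LHX3 features were highest in ampullary cells, while SOX2 and NEUROD1 features were highest in brain. The FOXI1 feature was higher in ampullary cells than in body skin, unlike the FOXI1 sum.

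Voltage-gated calcium channels carry the inward current of receptor cells, and the series allowed their pore-forming genes to be compared. Of the 10 listed genes 8 were matched, and shares are of the matched genes alone. In ampullary cells the CACNA1D group, which encodes the L-type channel CaV1.3, took 96.3% of the family's counts (95.6 to 96.8, exact binomial), or 3624 of 3765. Its main feature (c71999_g2) matched the CACNA1D sequence at 83.4% over 1686 residues and had 141 CPM (136 to 145) in ampullary cells, 46.2 in brain, 14.6 in body skin and 17.97 in muscle. That was 3.05-fold (2.81 to 3.31) above brain, below the ratio of 4 set for a call. In brain CACNA1D held 58.7% of the family, beside CACNA1C with 16.7% and CACNA1F with 12.4%, and in muscle CACNA1S, the skeletal muscle channel, held 55.0%. In body skin CACNA1D held 97.3% (93.9 to 99.1), or 182 of 187 counts, so its share there was no lower than in ampullary cells. The share in ampullary cells was 58.6% with the authors' TPM in place of counts, and the summed CACNA1D features, at a log2 ratio of 0.80 over brain by counts, stood at -0.54 by TPM. The auxiliary subunit feature closest to CACNB2 (c63418_g1) had 56.2 CPM in ampullary cells and 57.8 in brain, a ratio of 1.03 (0.944 to 1.12) of brain over ampullary cells that was not detectable as a difference at this depth. The CACNB2 sum over 4 features was 60.7 in ampullary cells and 173.5 in brain, 2.86-fold (2.68 to 3.05) higher in brain. As a list, the 6 measured calcium channel subunits did not stand apart, at percentile 23.3 of matched random lists, or 65.1 with a pseudocount of 0.1.

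Potassium channels repolarize the receptor membrane. Of the 26 listed genes 12 were matched, and the rest have no value and no part in the shares. KCNMA1, the large-conductance calcium-activated channel, took 66.6% (65.7 to 67.4) of the family's counts in ampullary cells, and a KCNA-type voltage-gated channel took 27.3% (26.6 to 28.1). The KCNMA1 share was 49.3% with the authors' TPM, and by counts it was 69.7% (66.4 to 72.9) in muscle, 12.7% in brain and 3.46% in body skin. The KCNMA1 feature (c59992_g1) had 341 CPM in ampullary cells, 101 in brain, 62.0 in muscle and 0.738 in body skin, a ratio of 3.38 (3.20 to 3.57) over brain. The KCNA-type feature (c70395_g3) had 140 in ampullary cells, 16.9 in brain, 0.871 in muscle and 0.082 in body skin, and was 8.31-fold (7.32 to 9.47) above brain by counts. It scored 645 bits against KCNA5 and 632 against KCNA3, so which member of the KCNA group it belongs to was left open. With the authors' TPM its order turned, with 26.2 in ampullary cells and 35.5 in brain, where the deposited mean transcript length was 881 bases against 5658 in ampullary cells. A KCNAB-type auxiliary subunit (c67262_g1) had 97.2 CPM in ampullary cells and 1, 1 and 0 counts in brain, body skin and muscle. Its score was 504 bits against both KCNAB1 and KCNAB2. The KCNAB1 sum was 97.2 in ampullary cells, 27.97 in brain and 23.4 in muscle, a ratio of 3.48 (3.14 to 3.86) over brain that fell to a log2 ratio of 0.15 by TPM, and the KCNAB2 sum was 8.08 in ampullary cells and 161 in brain. Brain led for most other channels, and 9 of the list's genes passed the rule there. KCNC1 had 194 CPM in brain and 0.081 in ampullary cells, KCND2 101 and 0.566, and KCNA1 90.5 and 0.242. The median of the 13 measured potassium channel genes was -1.38 on the log2 scale, at percentile 0.02 of matched random lists. For sodium channels 2 genes were matched, too few for a list value, and SCN2A-like features summed to 38.3 CPM in ampullary cells and 322 in brain.

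**Figure D2:**
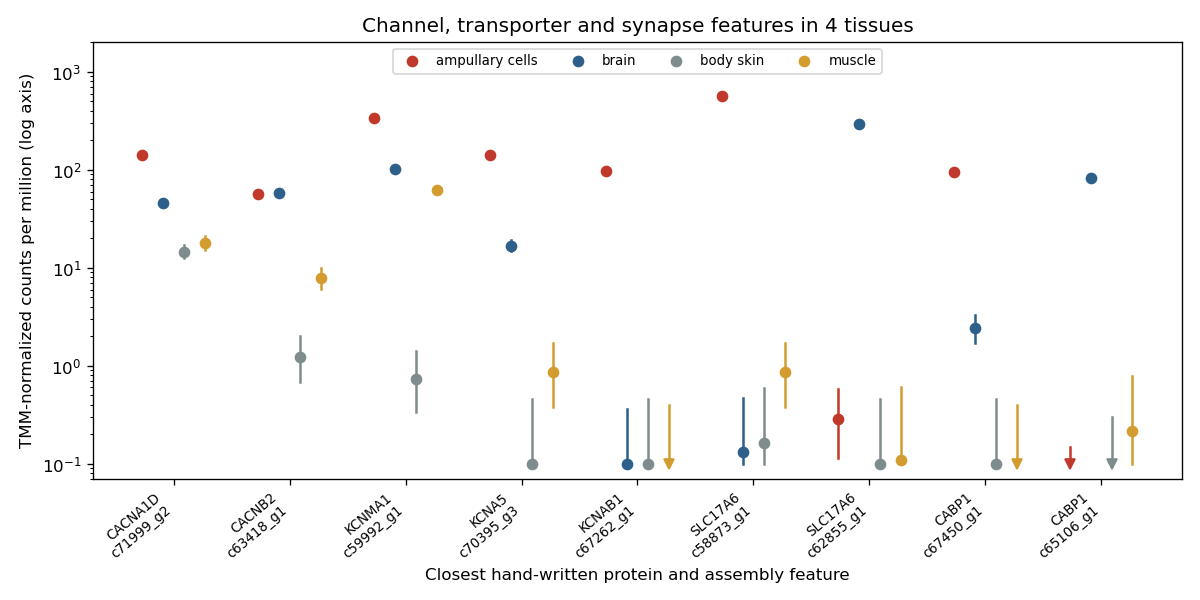
TMM-normalized CPM (log axis) of 9 channel, transporter and calcium-sensor features in the 4 tissues, 1 library each; lines are 95% exact Poisson intervals for counting error only, values under 0.1 are drawn at 0.1, and triangles mark a count of 0. The KCNMA1 feature stood at 341 in ampullary cells and 101 in brain, and the 2 SLC17A6-like and the 2 CABP1-like features were each split between ampullary cells and brain.

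Ampullary cells and brain are both excitable, and 1605 features were at least 4-fold higher and 3050 at least 4-fold lower in ampullary cells than in brain. Genes of transmitter release went in both directions. A vesicular glutamate transporter feature (c58873_g1) had 571 CPM in ampullary cells and 0.131 in brain, while a second one (c62855_g1) had 0.283 and 291. Both lay closest to SLC17A6, and the first scored 827 bits against it and 801 against SLC17A8, the transporter of inner hair cells. A CABP1-like feature (c67450_g1), of a family of calcium sensors that tune calcium channels, had 94.3 against 2.42 in brain, a ratio of 38.99 (28.2 to 55.5). Another (c65106_g1) had no counts in ampullary cells and 81.9 in brain, at least 675-fold higher there. CTBP2 (c65725_g1), whose locus also encodes the ribbon protein RIBEYE, had 338 against 83.6 in brain (437 against 136 as a sum), and CTBP1 (c71857_g1) had 313 against 33.7. For conventional release genes of neurons the highest-scoring features were lower in ampullary cells. SNAP25 (c70299_g1) had 4.36 CPM against 447 in brain, and SYT1 (c64111_g1) 0.687 against 686. As sums, which hold related genes too, they had 110.8 against 486 and 79.7 against 782. The 10 measured genes of the ribbon synapse and exocytosis list had a median of -0.42, at percentile 7.76. With the highest-scoring feature per gene these were -1.29 and 0.02, with the most-counted feature -0.71 and 1.15, and with TPM -0.49 and 1.39. The 11 measured neuron markers lay at percentile 0.50, and STMN2 (c107787_g1) had 0.081 against 1294, or 56.5 against 1942 as a sum. Brain carried the glial marker S100B at 3551 CPM, against 34.3 in ampullary cells. GLUL (c48046_g1) was also higher in brain, at 1605 against 1049.7, as was the SLC1A3 sum, at 1319 against 655. One SLC1A3-like glutamate uptake feature (c71576_g1) went the other way, with 315 in ampullary cells and 0.392 in brain, and so did PMP22, with 162 and 63.4.

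Against body skin, the tissue without electroreceptors, 2504 features were at least 4-fold higher and 2396 at least 4-fold lower in ampullary cells. With library totals in place of TMM these became 3268 and 1771, so the share of higher features moved from 51.1% to 64.9%. The AMPA-type receptor feature GRIA2 (c69104_g1) had 213 CPM in ampullary cells and 0.410 in skin, and KCNMA1 had 341 and 0.738. SCN2A sums stood at 38.3 in ampullary cells and 40.01 in skin, and KCNJ10 at 4.04 and 14.7. Keratin features went both ways. The KRT14-like feature (c53712_g1) had 20.8 in ampullary cells and 3729.5 in skin, and the KRT8-like feature (c58516_g1) 1977 and 9933, at 52.3% and 50.4% identity. With matches of at least 65% identity alone the KRT8 log2 ratio over the highest other tissue turned from -2.41 to 0.56. Fewer than 3 epithelial markers then reached 50 counts in any library, so no list value was given there. The KRT18-like feature (c34425_g1) was higher in ampullary cells, at 143 against 30.7. Markers of connective tissue were abundant in ampullary cells in part. The COL1A1 and COL2A1 sums were highest there, while SPARC had 571 against 2827 in brain and VIM 387 against 1074. COL1A2 had 1 count in ampullary cells and none elsewhere. The COL1A1-like feature (c54967_g1) had 2681 in ampullary cells, 545 in skin, 756 in muscle and 212 in brain. Against the mean of the 3 other tissues, the 4 measured connective tissue markers lay at percentile 99.7 of matched lists, the 4 measured epithelial markers at 99.8 and the 7 measured glial markers at 99.6. None of these markers passed the rule in ampullary cells, while 2 of the epithelial markers passed in body skin, and 4 of the glial and 1 of the connective tissue markers in brain. Against skin alone 3 of the epithelial markers, CDH1, KRT14 and KRT8, were lower in ampullary cells. The CDH1 sum, at 413 CPM in ampullary cells over 7 features, mixes features with different tissue patterns, given in the closing section. The glial percentile was 55.3, over 3 genes, with the earlier-written sequences alone. The 7 measured ion transport genes had a median of 0.35 at percentile 94.7, and 0.98 at 99.3 with TPM; over the alternatives the percentile ranged from 91.2 to 99.3. The sodium pump subunit ATP1B1 had 983 in ampullary cells and 170 in skin, while CA2 had 249 and 444 and SLC12A2 56.1 and 124.

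Against muscle, 2541 features were at least 4-fold higher and 1646 at least 4-fold lower in ampullary cells, 60.7% of them higher. Over 10291 features, library totals moved the median log2 ratio by 0.60 against muscle and 0.44 against body skin, and TPM moved it by 0.99 against muscle and -0.41 against brain. The split depended on the scaling, at 3879 and 1192 features (76.5% higher) with library totals and 4637 and 876 (84.1%) with the authors' TPM. Of the 14 measured muscle markers 10 passed the rule in muscle, their median was -3.29, and the list lay at percentile 0. PVALB-like features, the fast muscle calcium buffers, summed to 25672 CPM in muscle and 2.51 in ampullary cells. CKM, the muscle creatine kinase, had 37054 and 14.6, TNNC2 13385 and 1.66, and ATP2A1, the calcium pump of the sarcoplasmic reticulum, 8158 and 1.82. Features labelled with other members of the list were not muscle-restricted. The ALDOA and TPM2 labels were highest in body skin, at 438 and 602 against 76.03 and 273.5 in muscle, and PYGM was 1.25-fold higher in muscle than in ampullary cells. Features labelled ALDOC, a related aldolase outside the list, summed to 11217 in muscle, 2563 in brain, 741 in ampullary cells and 293 in body skin. The ALDOA value therefore does not stand for all aldolase of muscle. The 20 features with the most counts over all libraries took 28.2% of the muscle counts and 9.02% of those of ampullary cells.

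For genes of general cell function, the 7 housekeeping genes lay at percentile 72.6 and the 5 ribosomal protein genes at 10.5, with EEF1A1 between 3879.9 and 4592 CPM in all 4 tissues. Sums for other housekeeping labels varied more, GAPDH from 55.8 in muscle to 833 in brain and ACTB from 1998 in ampullary cells to 7429 in body skin. These sums hold matched features alone, so a feature missed by an unchecked sequence, such as one for GAPDH in muscle, would not be counted. The 8 measured mitochondrial energy genes lay at percentile 91.8, and MT-CO1 ranged from 10513 in brain to 11993 in body skin. For the calcium buffer and pump list the median of 8 measured genes was -0.78, at percentile 0.72, and 35.1 with matches of at least 65% identity. Of the mechanotransduction list, 1 gene was matched and none reached 50 counts. Many list genes had no sequence written and were never searched for, so an unmatched gene is not shown to be absent. No value is given for blood, leukocyte, endothelial or pigment markers, for which no gene was measured at 50 counts.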

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

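No paired analysis was possible because each tissue had 1 library and no test was made, and no replicate could be left out. Equal depth, the feature with the highest alignment score and the earlier-written sequences alone were chosen after seeing the data; the other alternatives were fixed before the data were examined. Under the settings fixed beforehand, for counts of features, family shares and lists, 79 values stayed within 1.5 times the count, or within the interval of the share, and 37 moved. For single genes 145 values stayed within their interval, 116 moved beyond it, and 2 at least 4-fold apart in the report turned direction. Under the settings added later these numbers were 15 and 1, then 56, 23 and 2. Counting intervals of abundant genes are narrow, so small shifts counted as moved.

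With library totals, 3879 features were higher in ampullary cells than in muscle. With TPM 399 features passed in muscle, 4637 were higher and 876 lower in ampullary cells than in muscle, the CACNA1D share was 58.6%, the KCNMA1 share 49.3%, and the KCNA5 log2 ratio over the highest other tissue turned to -0.43. Genes under 4-fold changed sign too, CACNA1D to -0.54 and ATP2B2 to -0.31 with TPM, and ATP2B2 to -4.82 and CABP1 to -6.37 with the highest-scoring feature. The mean length of the KCNA5 feature differed between the libraries, 881 bases in brain and 5658 in ampullary cells, and TPM divides by length. For the other values under TPM the cause was not tested.

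A stricter or looser rule changes counts by its construction. With at least 200 counts 1374 features passed in brain and 434 in muscle, and 1765, 1594 and 857 were lower in ampullary cells than in brain, body skin and muscle. At a ratio of at least 2, 1673, 4216, 2876 and 1428 features passed in ampullary cells, brain, body skin and muscle. Higher and lower in ampullary cells were then 4277 and 5817 against brain, 5471 and 5063 against body skin, and 6334 and 3326 against muscle. At a ratio of at least 8, 295, 1146, 580 and 338 features passed in the same order of tissues, with 744 and 1496 against brain, 1136 and 981 against body skin, and 1051 and 789 against muscle. A pseudocount of 0.1 CPM gave 994 features in ampullary cells, and 2533, 3869 and 4060 higher than in brain, body skin and muscle.

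The CACNA1D share was 97.6% with the most-counted feature per gene, 97.6% with 65% identity and 97.7% with the highest-scoring feature. The KRT8 log2 ratio turned to 0.56 with 65% identity and to 0.020 with the highest-scoring feature. OCM turned to -0.10 with the highest-scoring feature, and each of these values rests on another feature of the same label. They include the pseudocount of 1 CPM, which shrinks the log2 ratio of features with few counts. A small value therefore does not show equal levels across the tissues. Fewer than 3 epithelial markers reached 50 counts in these settings. The earlier-written sequences alone put the transcription factor list, with 5 genes, at a median of 3.27 and percentile 99.99. At equal depth 609, 2255, 1329 and 729 features passed in ampullary cells, brain, body skin and muscle. A feature without counts had an upper Poisson limit of 0.149 CPM in ampullary cells and 0.402 in muscle.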

Other observations

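The tests of skin and of brain RNA below were chosen after the result was seen; the test of depth was set before. The features and sequences in the first paragraph were picked after their values were seen, except where the rule for named genes gave them. Features closest to CDH1, the gene of the epithelial adhesion protein E-cadherin, had different tissue patterns. One (c47113_g1) had 241 CPM in ampullary cells, 84.4 in brain and 2.38 in body skin, at 50.2% identity, and another (c61244_g1) had 170 in ampullary cells and 1328 in body skin. Which cadherin gene each of these features belongs to was left open. A forkhead feature closest to FOXI1 (c36400_g1) had 16.6 CPM in ampullary cells and 0.654 in brain and no counts in body skin or muscle, at 63.3% identity over 90 residues. The feature closest to FOXI1 at full identity over 100 residues (c51027_g1) had 7.52 against 0.574 in body skin, while the FOXI1 sum was highest in body skin. KCNQ1 (c65432_g1), a potassium channel of secretory epithelia, had 16.4 CPM in ampullary cells and 3.53 in body skin.

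Some of the most tissue-restricted features matched none of the written sequences. In ampullary cells c59006_g2 had 2925 CPM against at most 1.31 elsewhere, and c50318_g1 had 740.2 against at most 0.656. In brain c65207_g4 had 1586 and c70014_g1 574, in body skin c50321_g1 had 1054 and c71513_g1 1185, and in muscle c61813_g1 had 20602 and c24093_g1 20098. Among matched genes the neurofilament NEFL had 286 CPM in brain and 1.70 in ampullary cells, the NMDA receptor gene GRIN1 139.6 and 0.283, the glycolytic enzyme ALDOA 438 in body skin and 39.8 in ampullary cells, and the troponin TNNI2 8345 in muscle and 3.07 in ampullary cells.

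The first pattern weighed was the number of features past the rule in ampullary cells, since that library was the deepest. With every library thinned to the smallest total 609 features passed, and full depth gave 1.04 times as many. The test decides nothing, because the ratio is set on CPM and 635 features also passed with no filter on counts. Under the main settings the count was also the lowest of the 4 tissues, so there it shows no excess to explain. It was above muscle under some alternatives, at 791 against 566 with library totals and 722 against 399 with TPM. The same held with at least 200 counts, a ratio of at least 2 and a pseudocount of 0.1. Brain and body skin had higher counts under each setting. An effect of depth and variation between animals stay open.

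The second was the abundance of collagen and simple-keratin features in the ampullary library, which may come from body skin taken along with the organs. The KRT14 level allowed a share of skin of 0.0081, and the smallest share needed, for KRT8, was 23.2 times that (21.4 to 25.3), with COL1A1 needing 606 times as much. COL1A1, COL2A1 and KRT18 stood at 4.91, 4.12 and 4.68 times their body skin level, which no share of skin can give. Their outcome was set by values already seen. The levels of KRT8, at 0.188 of skin, and of KRT14 had been seen too, so no gene was left to decide. The comparison therefore describes known values. With KRT8 matches of at least 65% identity alone its own value was 198 times (130.04 to 307), and without KRT8 the smallest was 509 for COL2A1. The wider interval of the 198 reflects fewer KRT8 counts, and its KRT14 share still used matches of at least 50% identity. The levels argue against skin like the sampled body skin as the whole source of these features. Skin next to the organs was not profiled and can differ in KRT14, and connective tissue or supporting cells of the organs stay open, and no biological explanation was tested.

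The third was the presence of GRIA2, CACNA1D, CACNB2 and KCNMA1 features in ampullary cells and brain, which could come from brain or nerve RNA. The median ampullary level of the 4 features was 2.01 times that in brain and the lowest, GRIA2, 0.577, while the neuron genes SNAP25, SYT1 and STMN2 stood at most at 0.977% of their brain level, by the feature with the highest alignment score of each gene. CACNA1D and KCNMA1 stood at 3.05 and 3.38 times brain, values already seen, so this median was above 1 whatever GRIA2 and CACNB2 gave. As sums the median was 1.12 times the brain level and CACNB2, the lowest, stood at 35.0%, above SNAP25 at 22.8% but below TUBB3, another listed neuron marker, at 40.2%, and GRIA2 is itself on that list. The TUBB3 sum was not particular to brain, at 732 CPM in muscle, 469 in body skin and 217 in brain. RNA like the sampled brain would bring all its abundant transcripts, and the NEFL and GRIN1 sums stood at 0.593% and 0.203% of brain, which argues against it as the whole source. Another brain region, and axons of the sensory nerve, were not profiled and stay open, as does expression of these genes by the receptor cells themselves, which was not tested apart.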
